A study of Homo sapiens with 12 samples.

How the data were processed

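The data are RNA sequencing libraries of the human cell line PC9 in 4 groups of 3: naive, gefitinib for 24 h, gefitinib for 9 d, and release for 3 d after 9 d of gefitinib. Per the labels' protocols, cells grew in DMEM with fetal bovine serum, RNA was extracted with a column kit, and libraries were made with a TruSeq protocol that selects polyadenylated mRNA. The labels give no gefitinib dose and do not say whether the 3 libraries of a group came from separate cultures. The p-values here therefore measure only the spread between these libraries, which may be technical.

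The deposited table gives, per the file headers, the raw count of each gene symbol in each of the 12 libraries and a second block of DESeq2-normalized counts. The count values were checked to be whole numbers with a different total in each library. The normalized signal was made by the authors from the same counts by dividing each library by 1 size factor, per the file headers and a check of the values, with factors from 0.851 to 1.17. All columns of values were read, and the number not used was 0; the normalized block served to check the counts and the size factors, and every test ran on the raw counts. The submitters' processing notes name TopHat2 2.0.10, HTSeq 0.6.1p1, DESeq2 1.6.3 and the genome build hg19, without stating the role or settings of each. The gene annotation, strand setting and any read filter are not given in the sources used here. Symbols were used as the table gives them. No coordinates are printed, since the table holds none and the reference at hand is of a later build. Reads of overlapping or near-identical genes, such as HLA, PSG, SAA, AKR1C and histone genes, may be assigned to a neighbour or a relative. The table holds 0 mitochondrially encoded genes.

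Of 23368 genes, 4424 had no count in any library. Genes were kept by the filterByExpr function of edgeR 4.0.16 in R 4.3.3, which left out 9394 and kept 13974. Library totals ran from 12915018 to 18142688 counts. The most abundant gene, EEF1A1, took 1.60% to 2.62% of a library. Counts were scaled by TMM and fitted in 1 robust quasi-likelihood model of all 12 libraries by group, with 8 residual degrees of freedom. The biological coefficient of variation was 0.0644. Each of 5 comparisons used edgeR's quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg over all tested genes. A gene was called at an adjusted p under 0.05, and calls of at least 2-fold were also counted. The SE of a log2 fold change is its size divided by the square root of F. CPM are scaled by TMM, and fold changes come from the model, so a fold can differ slightly from the ratio of mean CPM. Where a group had 0 counts, a lower bound on the fold was taken from a floor of 3 counts over the group, and where it had 1 to 3 counts a ratio is given with its exact 95% interval. These bounds and intervals cover counting error only.

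Groups, comparisons, gene lists and the rule for naming genes were fixed before the data were examined. There were 43 gene lists with 934 members, of which 918 were in the table, covering 864 distinct symbols, and 41 lists had at least 5 tested members. Each was tested with camera of limma 3.58.1 with its preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over 205 list tests. Camera asks whether a list moved relative to all other genes. It was repeated with a correlation estimated from the libraries, and fry was run with its directional p, which asks whether the genes of a list move 1 way on balance and makes no comparison with other genes. For each list the members higher, lower and not called were counted, over all genes tested and adjusted over the list alone. No called list had a median, a mean and a test that differed in sign, and medians were the same with genes of 0 counts set at their bound.

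Genes are named by 3 rules. The first takes EGFR, IRS1, IRS2, ERBB2 and ERBB3 in each comparison. The second takes, for each comparison with naive cells and for release against 9 d, the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM, a regular gene symbol, and 3 libraries of 1 group beyond the 3 of the other. The third takes up to 4 called members per list and comparison with the largest change and a mean of at least 1 CPM. Not every gene so named is described, and 2 of them are not reported here. Members that were not called are given as values.

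Overlaps of calls between comparisons are set beside the product of both numbers of calls over the number of genes tested, and beside 20 simulations of unchanged groups that share the same libraries. The groups are too small to divide the shared libraries between comparisons. Distances are the root mean square over the 500 genes of highest variance of differences in log2 CPM with a prior count of 2.

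The alternatives tried were DESeq2 1.42.0, limma-voom, median-ratio (RLE) size factors, library totals alone, no filter on low counts, filters of 1 and of 10 CPM in at least 3 libraries, only the 6 libraries compared, an adjusted p under 0.01, leaving out each library in turn, all tested genes for the distances, and for the lists an estimated correlation and fry. A block of libraries by their order in the table was added after the data were seen. With library totals the median log2 fold change of all genes moved from 0.032 to 0.11 at 24 h, from 0.025 to 0.173 at 9 d and from 0.018 to 0.118 after release against naive cells, and with RLE by at most 0.042. The closing section gives their effects.

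The steps were tested on simulated data. For a simulated gefitinib 24 h against naive, with 13142 genes and known changes, the test recovered 76.2% of 63 genes changed 1.5-fold, 87.1% of 62 changed 2-fold and all 65 changed 4-fold. Of 204 calls 8 (3.90%) were of unchanged genes, and a simulated unchanged comparison gave 0 calls. Both changed lists were called, and 0 of 37 unchanged lists. Genes were drawn independently of one another, and most were unchanged. In the real comparison at 24 h 77.3% of genes were called, and the estimated correlation of the G2/M list was 0.937. The simulated list calls and the 3.90% share therefore do not carry over to the real data.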

Results

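PC9 is a human lung adenocarcinoma cell line that carries an activating mutation of EGFR, the epidermal growth factor receptor, and gefitinib is a small molecule that inhibits the EGFR kinase. Polyadenylated RNA of PC9 cells was sequenced in 4 groups of 3 libraries. The groups were naive (untreated) cells, cells under gefitinib for 24 h, cells under gefitinib for 9 d, and cells kept without the drug for 3 d after 9 d of gefitinib (release). The series title concerns phosphorylation of IRS1, an adaptor protein of the insulin and IGF receptors, and the persistence of cancer cells under EGFR inhibition. RNA counts measure neither phosphorylation nor survival. The table held 23368 gene symbols. Of these genes, 13974 had enough counts to be tested. Library totals were 15409626, 17386729 and 16889219 counts in naive replicates 1 to 3, and 14634272, 15803394 and 14617686 counts at 24 h. They were 16812037, 16620269 and 16758277 counts at 9 d, and 15503160, 12915018 and 18142688 counts after release. Levels are given in CPM, the count of a gene scaled to the size of its library, as mean ± SD, and log2 fold changes as estimate ± SE. Both have n = 3 libraries per group.

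The 12 libraries fell into their 4 groups. Over the 500 genes of highest variance, the distance between group centroids (root mean square of log2 CPM differences) was 3.13 between naive and 24 h, 3.60 between naive and 9 d, and 2.95 between naive and release. Cells at 9 d and after release were the nearest pair, at 1.12. Libraries lay 0.23 to 0.33 from the centroid of their own group. The first principal component held 60.8% of the variance and placed the release libraries, at scores of 11.3 to 18.9, between the 9 d libraries, at 31.0 to 33.0, and the naive libraries, at −49.6 to −47.2. The 24 h libraries also lay between these groups on the first component, at −1.07 to 3.74. The second component, with 34.5% of the variance, set the 24 h libraries apart at scores of −40.0 to −37.9. On the second component the release libraries, at 18.1 to 22.2, lay beyond both the naive libraries, at 8.78 to 12.4, and the 9 d libraries, at 7.25 to 8.57. Release replicate 3 lay apart from replicates 1 and 2, at a first score of 11.3 against 17.8 and 18.9. Its counts differed from theirs by 3.75 and 3.84 times the counting variance in the median gene, against 1.49 between replicates 1 and 2. Pairs of 24 h libraries gave 3.15 to 3.65, pairs of naive libraries 1.94 to 2.78, and pairs at 9 d 1.38 to 2.08, so the 24 h libraries differed about as much among themselves.

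**Figure D1:**
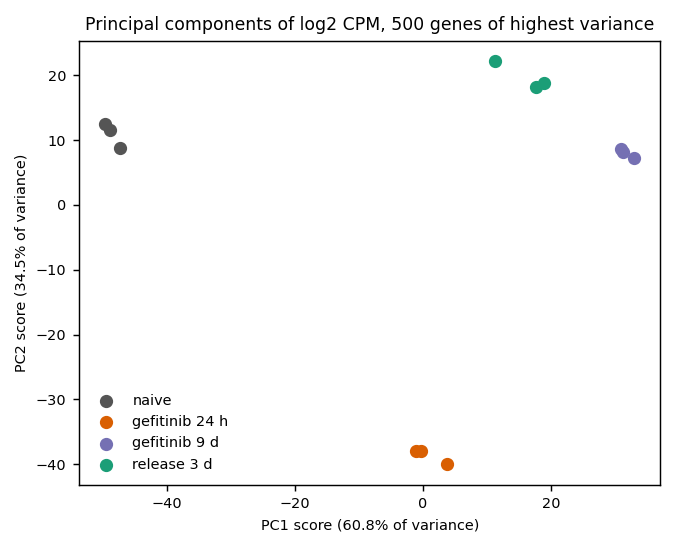
Scores of the 12 libraries on the first and second principal components of log2 CPM over the 500 most variable genes, 1 point per library, coloured by group, with the percent of variance on each axis. The libraries of each group lie together. The release and the 24 h libraries lie between the 9 d and the naive libraries on the first component, but not on the second.

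The comparison of 24 h of gefitinib with naive cells asks which transcripts change early under EGFR inhibition. Transcripts that report ERK signalling fell steeply. DUSP6, a phosphatase that switches off ERK and is itself induced by it, fell from 70.5 ± 3.21 CPM to 0.779 ± 0.237 CPM (log2 fold change −6.49 ± 0.21, adjusted p = 3.49e-13), and the ERK-induced transcription factor ETV5 fell from 48.3 ± 2.73 to 0.688 ± 0.0745 CPM (−6.11 ± 0.19, adjusted p = 6.32e-14). Of 21 tested genes of the MAPK/ERK output list, 20 fell and 1 rose, with a median log2 fold change of −2.81 (by camera, which sets a list against all other genes, adjusted p = 5.03e-09, adjusted p = 0.265 with an estimated correlation). FOSL1, a partner of JUN in the AP-1 transcription factor, fell from 118 ± 13.7 to 2.02 ± 0.805 CPM (−5.86 ± 0.30). TERT, the catalytic subunit of telomerase, fell from 14.5 ± 3.65 to 0.088 ± 0.0339 CPM (−7.23 ± 0.36), and TNS4, a focal adhesion protein, by 6.35 on the log2 scale. IL1RL1, a receptor of the interleukin-1 family, fell by 6.14. HBEGF, a ligand of EGFR, dropped by 4.11 and ERRFI1, a feedback inhibitor of EGFR, by 2.44.

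Transcripts of the receptors themselves moved apart. EGFR fell from 782 ± 50.1 to 458 ± 11.4 CPM (−0.77 ± 0.059, adjusted p = 1.86e-09), and IRS1 fell 4.02-fold, from 100.6 ± 8.58 to 24.96 ± 3.43 CPM (−2.01 ± 0.097, adjusted p = 7.86e-12). ERBB3, a receptor that signals through PI3K, rose 3.92-fold to 383 ± 8.94 CPM (1.97 ± 0.074, adjusted p = 2.98e-13), and its partner ERBB2 rose 2.15-fold to 213 ± 9.20 CPM (1.10 ± 0.063). IRS2, a second insulin receptor substrate, was 88.8 ± 6.04 CPM against 88.0 ± 1.70 CPM and did not pass the test (0.01 ± 0.057, adjusted p = 0.831). Among FOXO target genes, which are held down by PI3K and AKT, 20 of 23 rose and 1 fell (median 1.98, adjusted p = 5.22e-07, adjusted p = 0.313 with an estimated correlation). PIK3IP1, an inhibitor of PI3K, rose from 2.58 ± 1.51 to 166 ± 21 CPM (6.02 ± 0.29). FBXO32, a ubiquitin ligase subunit of the FOXO programme, rose by 3.34 ± 0.14. BMF, a BH3-only protein that promotes apoptosis, rose from 7.26 ± 1.34 to 108 ± 1.29 CPM (3.90 ± 0.20), and BCL2L11, which encodes BIM, from 24.96 ± 2.72 to 59.2 ± 2.41 CPM (1.24 ± 0.073). BCL2L1, which encodes the survival protein BCL-XL, fell by 1.49 ± 0.057 on the log2 scale. Neither apoptosis list was called: pro-apoptotic genes rose in 5 of 11 cases and fell in 4 (median −0.14, adjusted p = 0.781), and anti-apoptotic genes rose in 4 of 8 and fell in 3 (median 0.11, adjusted p = 0.857). BAX and BAK1, which promote apoptosis, fell by 0.66 and by 0.85, and CFLAR, BIRC2 and BIRC3, which restrain it, rose by 0.97, 0.72 and 0.85.

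Genes of proliferation and growth were lower after 24 h of gefitinib. In the list of G1/S genes 30 of 31 fell and 0 rose (median −2.13, adjusted p = 1.72e-11, adjusted p = 0.34 with an estimated correlation). CDC25A, the phosphatase that activates CDK2, stood at −3.71 ± 0.13, and UHRF1, which keeps DNA methylation through replication, at −2.90 ± 0.14. Of 32 G2/M genes 31 fell and 0 rose (median −1.10, adjusted p = 2.06e-06, adjusted p = 0.536 with an estimated correlation). The mean log2 CPM of this list was 5.52 in 24 h replicate 3 and 6.22 and 6.21 in replicates 1 and 2, against 7.13 to 7.17 in naive libraries. CCNA2, which encodes cyclin A, fell by 1.69 ± 0.18. All 27 MYC target and ribosome biogenesis genes fell, with a median of −1.86 (adjusted p = 4.61e-12, adjusted p = 0.32 with an estimated correlation). ODC1, the entry enzyme of polyamine synthesis, dropped from 263 ± 27.8 to 24.5 ± 1.93 CPM. Glycolytic genes fell in 16 of 20 cases and rose in 3 (median −0.98, adjusted p = 0.000376, adjusted p = 0.33 with an estimated correlation). ENO1, an enolase, fell from 2321 ± 18 to 650.0 ± 50.3 CPM. Of 26 genes of the amino acid starvation (ATF4) list 19 fell and 5 rose (median −0.63, adjusted p = 0.00619, adjusted p = 0.34 with an estimated correlation). PSAT1, an enzyme of serine synthesis, fell by 2.58 ± 0.11.

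Other groups rose within 24 h. Of 23 cholesterol synthesis genes 21 rose and 0 fell (median 1.03, adjusted p = 0.00011, adjusted p = 0.536 with an estimated correlation). INSIG1, a sterol-regulated retention protein, was at 393 ± 19.6 CPM against 122 ± 46.2 CPM (1.70 ± 0.21). Autophagy and lysosome genes rose in 31 of 37 cases and fell in 4 (median 0.77, adjusted p = 3.77e-06, adjusted p = 0.32 with an estimated correlation). GABARAPL1, an autophagosome protein, rose from 18.5 ± 1.14 to 150 ± 15.9 CPM. Of 31 epithelial and junction genes 26 rose and 3 fell (median 0.57, adjusted p = 5.29e-05, adjusted p = 0.277 with an estimated correlation). MUC1, a surface mucin, rose by 4.27 ± 0.12 and ELF3, an epithelial transcription factor, by 2.14 ± 0.096. All 11 complement and acute phase genes rose (median 2.61, adjusted p = 0.000376, adjusted p = 0.294 with an estimated correlation). CFB, complement factor B, rose from 6.67 ± 1.26 to 69.2 ± 2.54 CPM. Type I interferon response genes rose in 23 of 36 cases and fell in 2 (median 1.03, adjusted p = 0.00133, adjusted p = 0.294 with an estimated correlation), and 13 of 14 antigen presentation genes rose (median 1.40, adjusted p = 0.000145, adjusted p = 0.33 with an estimated correlation). TNFSF10, the death receptor ligand TRAIL, rose 154-fold, from 0.302 ± 0.0928 to 47.1 ± 6.19 CPM, and TAC3, the neurokinin B precursor, had 0 counts in the naive libraries and was at least 81.5-fold higher at 24 h, from a floor of 3 counts over the naive group. ALPPL2, a germ cell alkaline phosphatase, rose from 6.06 ± 0.366 to 760.1 ± 86.6 CPM.

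At 24 h 5464 of the 13974 tested genes were higher and 5335 lower than in naive cells by edgeR's quasi-likelihood test, 2360 and 1793 of them by at least 2-fold. In 78.3% of tested genes the 3 libraries of one group lay beyond the 3 of the other, where chance gives 10%. By camera 9 lists were called higher and 6 lower out of 41, and with an estimated correlation 0 were called. Without 24 h replicate 3, 5277 genes were higher and 5200 lower. Adjusted over the list alone, the counts of members differed in 1 list, by 1 member. Scaling by library totals, with which the median of all genes at 24 h moves by 0.079, to 0.11, gave a share of higher calls of 55.2%, against 50.6% here.

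The comparison of 9 d of gefitinib with naive cells asks what sets apart the cells present after prolonged inhibition. FN1, the matrix protein fibronectin, rose from 96.7 ± 10.0 to 4699 ± 159 CPM (5.60 ± 0.11, adjusted p = 2.47e-15). The mesenchymal list to which FN1 belongs was not called, with 11 of 21 genes higher and 6 lower (median 0.69, adjusted p = 0.16). HLA-B, which presents peptides to T cells, rose from 4.44 ± 0.487 to 445 ± 27.4 CPM (6.64 ± 0.17, adjusted p = 1.44e-12). IRS1 stayed low at 24.7 ± 2.82 CPM, 4.08-fold lower than in naive cells (−2.03 ± 0.096, adjusted p = 7.93e-12). EGFR was 540.3 ± 32.4 CPM (−0.53 ± 0.059), ERBB2 199 ± 3.96 CPM (1.00 ± 0.063) and ERBB3 151 ± 0.596 CPM (0.63 ± 0.073), and all passed the test. IRS2 was lower, at −0.24 ± 0.057 (adjusted p = 0.0011), and with library totals it was −0.09 and not called (adjusted p = 0.151, with 0.000229 to 0.151 over all alternatives). HMGA2, a chromatin protein of embryonic and tumour cells, fell from 272 ± 10.5 to 8.97 ± 0.583 CPM (−4.92 ± 0.21), and MUC5B, an airway mucin, from 155 ± 15.6 to 0.589 ± 0.283 CPM (−8.02 ± 0.27).

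Interferon response genes were higher nearly throughout at 9 d. Of 36 members 35 rose and 1 fell (median 1.77, adjusted p = 5.11e-09, adjusted p = 0.249 with an estimated correlation). IFI6 rose from 0.233 ± 0.0622 to 40.7 ± 7.21 CPM (7.39 ± 0.23) and MX2, an antiviral GTPase, by 5.05 ± 0.30. All 14 antigen presentation genes rose (median 2.31, adjusted p = 4.19e-07, adjusted p = 0.294 with an estimated correlation). Reads of near-identical HLA genes can be assigned to the wrong member, and B2M, the invariant class I chain outside that family, rose 5.76-fold to 1273 ± 9.56 CPM. Of 19 NF-kB and inflammatory genes 11 rose and 3 fell (median 0.69, adjusted p = 0.0197, adjusted p = 0.298 with an estimated correlation). IL6, a cytokine, rose from 0.618 ± 0.320 to 17.02 ± 2.49 CPM and ICAM1, an adhesion receptor for leukocytes, from 41.5 ± 7.15 to 575 ± 23.1 CPM. Complement genes rose in 10 of 11 cases and fell in 1 (median 3.69, adjusted p = 0.000376, adjusted p = 0.294 with an estimated correlation). C1S, a protease of the classical pathway, rose by 4.55 ± 0.16. UBD, an interferon-induced ubiquitin-like protein, had 2 counts in the naive libraries and 764 at 9 d, a ratio of 341 (95% counting interval 94.2 to 2820). Markers of other cell types moved in different directions. The fibroblast transcripts DCN and LUM rose from 0 and 0.021 CPM to 3.65 and 2.30 CPM, and COL1A1 from 5.78 to 21.75 CPM, while COL1A2 was at 0.08 CPM and COL3A1 at 0.02 CPM. The leukocyte transcript ITGAM rose from 0.359 ± 0.113 to 7.33 ± 0.411 CPM, CSF1R from 0.0868 ± 0.0428 to 2.12 ± 0.527 CPM, LAPTM5 fell from 34.5 ± 3.29 to 5.06 ± 0.848 CPM, and the endothelial transcript PECAM1 fell from 19.8 ± 1.88 to 3.56 ± 0.493 CPM.

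At 9 d all 31 G1/S genes fell (median −1.90, adjusted p = 3.71e-12, adjusted p = 0.334 with an estimated correlation), as did all 32 G2/M genes (median −2.16, adjusted p = 2.76e-11, adjusted p = 0.445 with an estimated correlation). MKI67, a marker of cycling cells, fell from 590.0 ± 8.76 to 108 ± 6.99 CPM (−2.44 ± 0.20). CDKN1A, which encodes the CDK inhibitor p21, rose from 6.72 ± 0.134 to 57.0 ± 0.484 CPM (3.08 ± 0.089), and CDKN2B, which encodes p15, from 48.8 ± 7.38 to 255 ± 4.36 CPM (2.39 ± 0.12). Both belong to the list of CDK inhibitors and RB family genes, which camera did not call. Of its 9 tested genes 4 rose and 4 fell (median 0.095, camera adjusted p = 0.602). All 9 tested replication-dependent histone genes rose (median 3.13, adjusted p = 9.88e-05, adjusted p = 0.265 with an estimated correlation). HIST1H2BD rose from 3.66 ± 0.766 to 45.7 ± 2.13 CPM and HIST1H2AC from 2.05 ± 0.570 to 20.7 ± 1.05 CPM. The other members of that list had too few counts to be tested. MYC target genes fell in all 27 cases (median −1.22, adjusted p = 3.04e-09, adjusted p = 0.34 with an estimated correlation). NOP56, a nucleolar protein of ribosome assembly, fell from 410.4 ± 30.3 to 97.9 ± 3.71 CPM.

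MAPK/ERK output genes fell in 17 of 21 cases and rose in 4 (median −1.92, adjusted p = 7.46e-05, adjusted p = 0.33 with an estimated correlation). DUSP6 was at 2.35 ± 0.434 CPM (−4.91 ± 0.17) and SPRY4, a feedback inhibitor of receptor signalling, at −4.45 ± 0.16. FOXO targets rose in 19 of 23 cases and fell in 2 (median 1.41, adjusted p = 2.55e-05, adjusted p = 0.33 with an estimated correlation). Of 24 YAP/TEAD targets 17 rose and 5 fell (median 1.20, adjusted p = 0.000557, adjusted p = 0.33 with an estimated correlation). CTGF, a matricellular protein, rose from 0.169 ± 0.0648 to 3.14 ± 0.176 CPM and ANKRD1 from 8.71 ± 0.845 to 76.8 ± 2.78 CPM. MMP14, a membrane-bound matrix protease, rose 19.9-fold to 337 ± 5.73 CPM, and MYL9, a myosin light chain, from 0.0868 ± 0.0428 to 19.1 ± 4.12 CPM. Autophagy and lysosome genes rose in 29 of 37 cases and fell in 3 (median 0.85, adjusted p = 6.83e-07, adjusted p = 0.32 with an estimated correlation). GABARAPL1 rose to 312 ± 4.13 CPM (4.08 ± 0.090).

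Glycolysis genes fell at 9 d in 16 of 20 cases and rose in 2 (median −1.21, adjusted p = 0.000148, adjusted p = 0.32 with an estimated correlation). LDHA, lactate dehydrogenase A, fell from 4294 ± 183 to 1266 ± 94.1 CPM, while the glucose transporter gene SLC2A3 rose 4.77-fold. Oxidative phosphorylation genes fell in 27 of 35 cases and rose in 2 (median −0.42, adjusted p = 7.45e-05, adjusted p = 0.462 with an estimated correlation), and NRF2 target genes fell in 16 of 24 and rose in 3 (median −0.58, adjusted p = 0.00112, adjusted p = 0.477 with an estimated correlation). AKR1B10, an aldo-keto reductase, fell from 1346 ± 125 to 201 ± 13.5 CPM. Commonly used reference genes fell in 12 of 15 cases and rose in 2 (median −0.49, adjusted p = 0.0032, adjusted p = 0.33 with an estimated correlation). GAPDH fell from 7926 ± 97.5 to 2877 ± 206 CPM (−1.46 ± 0.072). Camera did not call the lists of cholesterol synthesis, in which 4 of 23 genes rose and 4 fell (median −0.01, adjusted p = 0.942), and fatty acid oxidation, in which 11 of 17 rose and 4 fell (median 0.47, adjusted p = 0.0957).

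At 9 d 5360 genes were higher and 5155 lower than in naive cells by edgeR's quasi-likelihood test, 2210 and 1448 of them by at least 2-fold. Camera called 9 lists higher and 8 lower, and 0 with an estimated correlation. Adjusted over the list alone, the counts of members differed in 3 lists, by at most 1 member. With library totals the median of all genes at 9 d moves by 0.147, to 0.173, and the share of higher calls is 59.9%, against 51.0% here.

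**Figure D2:**
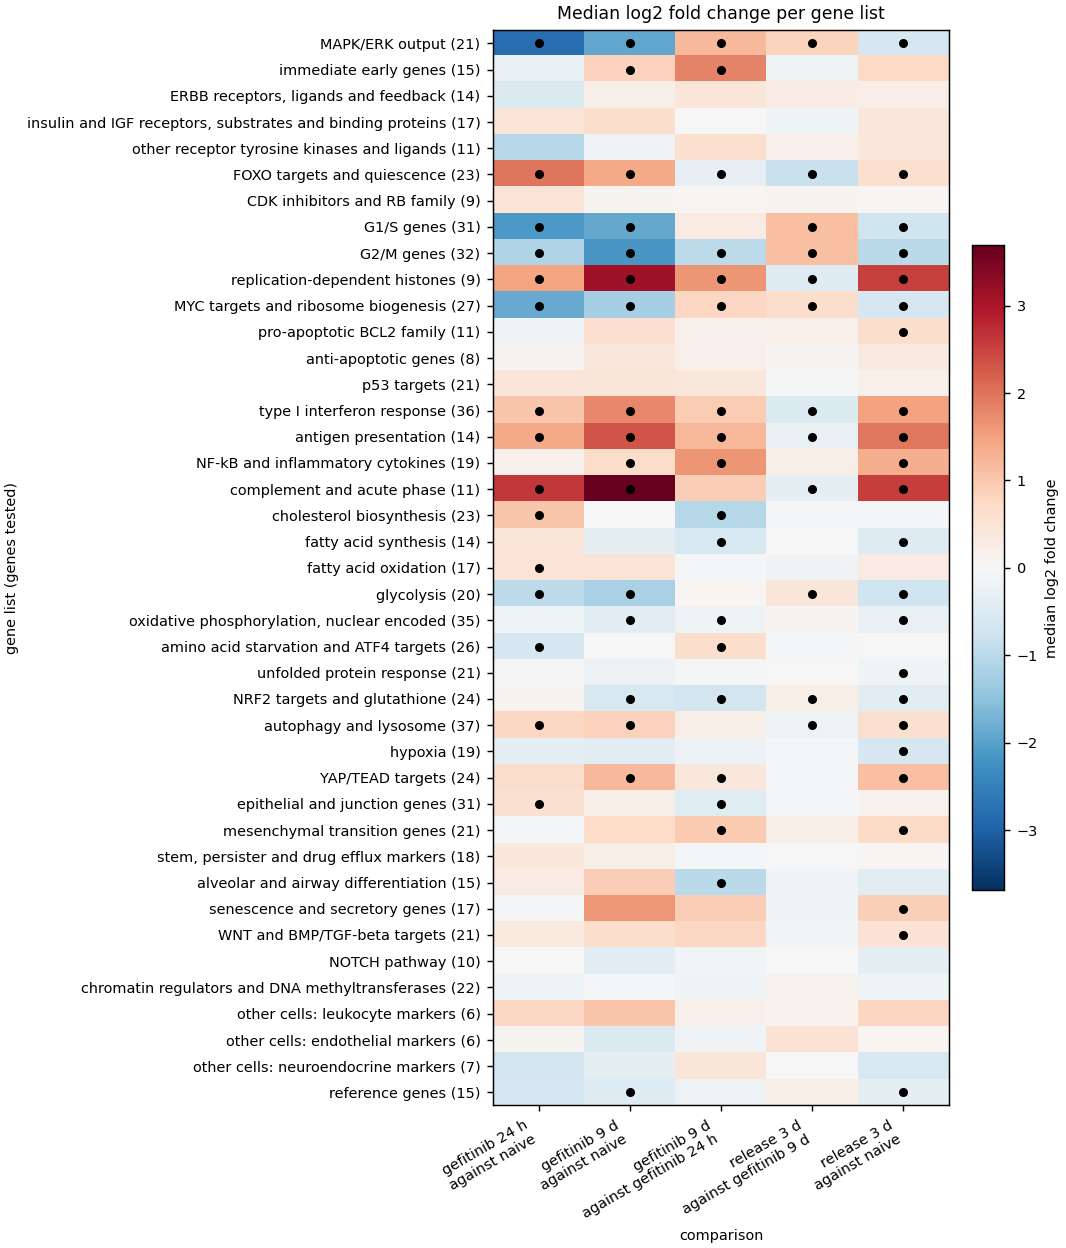
Median log2 fold change of each gene list (vertical axis, number of tested genes in brackets) in the 5 comparisons (horizontal axis), with a dot where camera with its preset correlation gave an adjusted p under 0.05. The G1/S list has medians of −2.13 at 24 h and −1.90 at 9 d against naive cells and 1.12 in release against 9 d.

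The comparison of 9 d with 24 h of gefitinib asks how cells under prolonged drug differ from cells early under the same drug. FN1 rose 34.9-fold from 135 ± 6.77 CPM (adjusted p = 8.38e-15), and ANKRD1, a stress-induced YAP target, 54.5-fold from 1.40 ± 0.0601 CPM. Of 21 mesenchymal transition genes 14 rose and 4 fell (median 0.97, adjusted p = 0.00599, adjusted p = 0.265 with an estimated correlation), while the fibroblast transcripts DCN and LUM were at 3.65 and 2.30 CPM against 0.09 and 0.668 CPM. Of 31 epithelial genes 4 rose and 19 fell (median −0.45, adjusted p = 0.00081, adjusted p = 0.298 with an estimated correlation). This was a partial return from the rise at 24 h. The mean log2 CPM of the list was 7.511 to 7.598 at 24 h and 7.15 to 7.215 at 9 d. In naive libraries it was lower, at 6.697 to 6.749. KRT8, a simple epithelial keratin, fell from 6692 ± 734 to 3047 ± 54.7 CPM. ATF3, a stress-induced transcription factor, rose from 0.681 ± 0.404 to 28.5 ± 5.23 CPM (5.35 ± 0.23) in an immediate early list of which 11 of 15 members rose and 0 fell (median 1.83, adjusted p = 0.000506, adjusted p = 0.33 with an estimated correlation).

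ERK output genes were less reduced at 9 d than at 24 h, with 17 of 21 higher and 2 lower (median 1.21, adjusted p = 3.89e-06, adjusted p = 0.304 with an estimated correlation). FOSL1 was at 27.6 ± 5.38 CPM against 2.02 ± 0.805 CPM and ETV5 at 8.16 ± 1.35 against 0.688 ± 0.0745 CPM. MYC targets were higher in 23 of 27 cases and lower in 2 (median 0.76, adjusted p = 3.89e-06, adjusted p = 0.465 with an estimated correlation). ODC1 rose by 2.55 ± 0.13. G2/M genes went the other way, with 28 of 32 lower and 0 higher (median −0.97, adjusted p = 1.62e-07, adjusted p = 0.52 with an estimated correlation). In the 9 d libraries the mean log2 CPM of this list was 4.92 to 5.18, against 5.52 in 24 h replicate 3 and 6.21 and 6.22 in the other 24 h libraries. KIF20A, a mitotic kinesin, was at 25.8 ± 2.65 CPM against 75.5 ± 21 CPM. Of 31 G1/S genes 18 were higher and 3 lower, and camera did not call the list (median 0.31, adjusted p = 0.0653). Sterol genes fell, 22 of 23 being lower and 0 higher (median −1.04, adjusted p = 1.64e-07, adjusted p = 0.459 with an estimated correlation). LSS, lanosterol synthase, fell from 342 ± 14.5 to 120.0 ± 9.58 CPM. In the fatty acid synthesis list 10 of 14 fell and 1 rose (median −0.60, adjusted p = 0.00159, adjusted p = 0.445 with an estimated correlation). SCD, the stearoyl-CoA desaturase, fell from 2452 ± 113 to 547 ± 42 CPM. ERBB3 was lower at 9 d than at 24 h (−1.34 ± 0.072), EGFR higher (0.24 ± 0.059, adjusted p = 0.00183), and IRS1 did not pass the test (−0.02 ± 0.10, adjusted p = 0.874).

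Interferon response genes were higher still at 9 d, 26 of 36 rising and 2 falling (median 0.94, adjusted p = 6.29e-05, adjusted p = 0.265 with an estimated correlation), and HLA-B was 26.4-fold above its 24 h level of 16.8 ± 3.40 CPM. Antigen presentation genes rose in 10 of 14 cases and fell in 2 (median 1.23, adjusted p = 0.00174, adjusted p = 0.411 with an estimated correlation). Of 19 NF-kB genes 14 rose and 2 fell (median 1.62, adjusted p = 0.00114, adjusted p = 0.265 with an estimated correlation). IL6 rose by 4.61 ± 0.23. All 9 tested histone genes were higher at 9 d than at 24 h (median 1.63, adjusted p = 0.000273, adjusted p = 0.265 with an estimated correlation). HIST1H1C, a linker histone, rose from 30.1 ± 2.84 to 108 ± 3.40 CPM. NRF2 targets fell in 18 of 24 cases and rose in 5 (median −0.69, adjusted p = 0.000101, adjusted p = 0.411 with an estimated correlation). GPX2, a glutathione peroxidase, fell from 540.2 ± 17 to 156 ± 8.72 CPM.

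Between both times on drug 4809 genes were higher and 4305 lower at 9 d by edgeR's quasi-likelihood test, 1195 and 1002 of them by at least 2-fold, and camera called 10 lists higher and 8 lower, 0 with an estimated correlation. Without 24 h replicate 3, 4549 genes were higher and 4166 lower. With library totals the share of higher calls is 59.5%, against 52.8% here. Counts adjusted over the list alone differed in 7 lists, by at most 1 member. Of the genes higher than in naive cells at 24 h, 3855 were also higher at 9 d. Independent calls would give 2096. Simulated unchanged groups that share the naive libraries gave a mean of 0, but with 0.35 calls per comparison they leave nothing to overlap and are no measure of agreement. Genes lower at both times numbered 3948, against 1968 for independent calls and 0 in the simulations. Part of the excess may come from the naive libraries that both comparisons share. Opposite calls were fewer than independent calls would give: 441 genes were higher at 24 h and lower at 9 d, against 2016, and 496 the reverse, against 2046. By at least 2-fold these were 38 genes, against 245, and 38, against 284.

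The comparison of release with 9 d of gefitinib asks what changes once the drug is withdrawn. Cell cycle genes rose as a whole: all 31 G1/S genes (median 1.12, adjusted p = 9.36e-20, adjusted p = 0.294 with an estimated correlation) and all 32 G2/M genes (median 1.10, adjusted p = 5.39e-14, adjusted p = 0.381 with an estimated correlation). TYMS, thymidylate synthase, rose 3.42-fold to 28.7 ± 6.23 CPM (1.77 ± 0.15, adjusted p = 6.48e-07) and CDC20, an activator of the anaphase-promoting complex, 2.82-fold to 100.5 ± 22.6 CPM (1.5 ± 0.19, adjusted p = 7.94e-05). ERK output genes rose in 16 of 21 cases and fell in 1 (median 0.83, adjusted p = 1.66e-07, adjusted p = 0.294 with an estimated correlation). DUSP6 rose 6.26-fold to 14.6 ± 3.87 CPM and SPRY4 5.52-fold to 14.7 ± 4.02 CPM. HMGA2 rose from 8.97 ± 0.583 to 89.5 ± 28.2 CPM (3.32 ± 0.21). Release replicate 3 was the furthest from 9 d in MKI67, at 319 CPM against 242 and 226 CPM in replicates 1 and 2, and in DUSP6, at 19.02 CPM against 11.98 and 12.7 CPM.

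EGFR rose to 756 ± 31.6 CPM (0.48 ± 0.059, adjusted p = 5.83e-06), while ERBB2 fell by 0.51 and ERBB3 by 0.63 on the log2 scale. IRS1 rose from 24.7 ± 2.82 to 31.1 ± 1.30 CPM (0.33 ± 0.10, adjusted p = 0.0122), a call that was lost without 9 d replicate 3 (0.24, adjusted p = 0.0709, with 0.00606 to 0.0709 over all alternatives), and IRS2 did not pass the test (0.05 ± 0.057, adjusted p = 0.53). MYC target genes rose in 24 of 27 cases and fell in 0 (median 0.66, adjusted p = 4.51e-11, adjusted p = 0.33 with an estimated correlation), and glycolysis genes rose in 14 of 20 and fell in 3 (median 0.44, adjusted p = 0.000881, adjusted p = 0.34 with an estimated correlation). LDHA rose to 2317 ± 155 CPM. NRF2 targets rose in 13 of 24 cases and fell in 1 (median 0.20, adjusted p = 0.0032, adjusted p = 0.518 with an estimated correlation). AXL, a receptor tyrosine kinase linked to drug tolerance, rose 2.66-fold to 185 ± 36.4 CPM, CD44, a hyaluronan receptor, 1.94-fold to 1296 ± 69.0 CPM, and ITGA6, a laminin-binding integrin, 4.82-fold to 455 ± 93.4 CPM. The list of stem, persister and drug efflux markers, to which CD44 belongs, did not rise as a whole (median −0.022). Its mean log2 CPM was 5.652 to 5.75 at 9 d and 5.621 to 5.64 after release.

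FOXO targets fell in 20 of 23 cases and rose in 1 (median −0.82, adjusted p = 5.37e-08, adjusted p = 0.294 with an estimated correlation). MXD4, an antagonist of MYC, fell by 1.14 ± 0.14. BMF dropped by 1.62 ± 0.17, from 100.3 ± 3.39 to 32.8 ± 9.57 CPM, with 21.8 CPM in release replicate 3 and 39.1 and 37.6 CPM in the others. Interferon response genes fell in 22 of 36 cases and rose in 2 (median −0.49, adjusted p = 3.21e-05, adjusted p = 0.265 with an estimated correlation). IFI6 fell from 40.7 ± 7.21 to 8.04 ± 1.35 CPM. Complement genes fell in 7 of 11 cases and rose in 1 (median −0.35, adjusted p = 0.00979, adjusted p = 0.34 with an estimated correlation). Autophagy and lysosome genes fell in 20 of 37 cases and rose in 3 (median −0.18, adjusted p = 0.000176, adjusted p = 0.373 with an estimated correlation). CTSF, a lysosomal protease, fell from 29.9 ± 0.988 to 11.3 ± 0.680 CPM. KRT4, a keratin of stratified epithelium, fell from 12.96 ± 4.03 to 1.09 ± 0.271 CPM (−3.57 ± 0.43), BPIFB1, a secreted airway protein, from 29.0 ± 5.87 to 4.17 ± 0.058 CPM, and TAC3 from 17.9 ± 2.03 to 3.47 ± 0.674 CPM.

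On release 3572 genes were higher and 2986 lower than at 9 d by edgeR's quasi-likelihood test, 406 and 291 of them by at least 2-fold, and 6 lists were called higher and 6 lower by camera, 0 with an estimated correlation. Without release replicate 3, 2894 were higher and 2203 lower. The share of higher calls depends on the scaling: 54.5% here, 47.7% with median-ratio size factors and 46.1% with library totals. Counts adjusted over the list alone differed in 11 lists, by at most 2 members.

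The comparison of release with naive cells asks what remains different 3 d after withdrawal. IRS1 remained 3.24-fold lower, at 31.1 ± 1.30 CPM against 100.6 ± 8.58 CPM (−1.69 ± 0.094, adjusted p = 1.54e-10), whereas EGFR (−0.05 ± 0.058, adjusted p = 0.48) and ERBB3 (0.00 ± 0.074, adjusted p = 0.992) did not pass the test, and ERBB2 was higher (0.50 ± 0.063). IRS2 was lower at −0.19 ± 0.057 (adjusted p = 0.00761), and with library totals it was −0.09 and not called (adjusted p = 0.171, with 0.000716 to 0.171 over all alternatives). FN1 was still 31.8-fold higher, at 3077 ± 425 CPM (4.99 ± 0.11), and HLA-B 89.3-fold higher, at 399 ± 63.8 CPM (6.48 ± 0.17). OLR1, a scavenger receptor for oxidised lipoprotein, was 154 ± 6.49 CPM against 1.24 ± 0.108 CPM, and MUC5B was 0.889 ± 0.543 CPM against 155 ± 15.6 CPM (−7.40 ± 0.26).

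Genes of the interferon response and antigen presentation were still higher than in naive cells. Of 36 interferon response genes 33 were higher than in naive cells and 0 lower (median 1.5, adjusted p = 5.38e-09, adjusted p = 0.249 with an estimated correlation), and all 14 antigen presentation genes were higher (median 1.94, adjusted p = 5.38e-09, adjusted p = 0.265 with an estimated correlation). NF-kB genes were higher in 12 of 19 cases and lower in 1 (median 1.34, adjusted p = 0.000176, adjusted p = 0.265 with an estimated correlation). ICAM1 was at 443 ± 53.2 CPM. YAP/TEAD targets were higher in 20 of 24 cases and lower in 3 (median 1.10, adjusted p = 1.12e-06, adjusted p = 0.284 with an estimated correlation). ANKRD1 was 15.7-fold higher at 137 ± 8.34 CPM. Mesenchymal genes were higher in 15 of 21 cases and lower in 3 (median 0.72, adjusted p = 0.00599, adjusted p = 0.265 with an estimated correlation), and complement genes in 8 of 11 with 1 lower (median 2.56, adjusted p = 0.00127, adjusted p = 0.32 with an estimated correlation). All 9 histone genes tested were higher (median 2.52, adjusted p = 1.24e-05, adjusted p = 0.265 with an estimated correlation). CDKN1A stood at 61.7 ± 6.70 CPM (3.20 ± 0.089). BIRC3, which NF-kB induces, was 10.5-fold higher at 260 ± 16.2 CPM. Of the fibroblast transcripts DCN was at 0.205 CPM, LUM at 0.366 CPM and COL1A1 at 16.8 CPM. ITGAM stayed at 7.08 ± 1.04 CPM and PECAM1 at 3.60 ± 0.651 CPM, while LAPTM5 was 13.2 ± 1.59 CPM.

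Cycle genes had not regained their naive level. Of 31 G1/S genes 29 were lower and 0 higher (median −0.74, adjusted p = 1.04e-07, adjusted p = 0.445 with an estimated correlation), and all 32 G2/M genes were lower (median −0.99, adjusted p = 5.42e-09, adjusted p = 0.503 with an estimated correlation), CDC20 at 100.5 ± 22.6 CPM against 236 ± 13.2 CPM. ERK output genes were lower in 15 of 21 cases and higher in 4 (median −0.62, adjusted p = 0.00263, adjusted p = 0.424 with an estimated correlation). DUSP6 was at −2.26 ± 0.13 and SPRY1 at −2.82 ± 0.10. FOXO targets were higher in 15 of 23 cases and lower in 3 (median 0.58, adjusted p = 0.00342, adjusted p = 0.477 with an estimated correlation). MYC target genes were lower in 22 of 27 cases and higher in 0 (median −0.63, adjusted p = 4.19e-07, adjusted p = 0.432 with an estimated correlation), and glycolysis genes in 15 of 20 with 1 higher (median −0.74, adjusted p = 9.88e-05, adjusted p = 0.32 with an estimated correlation). Hypoxia genes were lower in 13 of 19 cases and higher in 4 (median −0.62, adjusted p = 0.00994, adjusted p = 0.518 with an estimated correlation). PDK1, which restrains pyruvate oxidation, was at 33.6 ± 1.64 CPM against 71.2 ± 8.07 CPM.

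**Figure D3:**
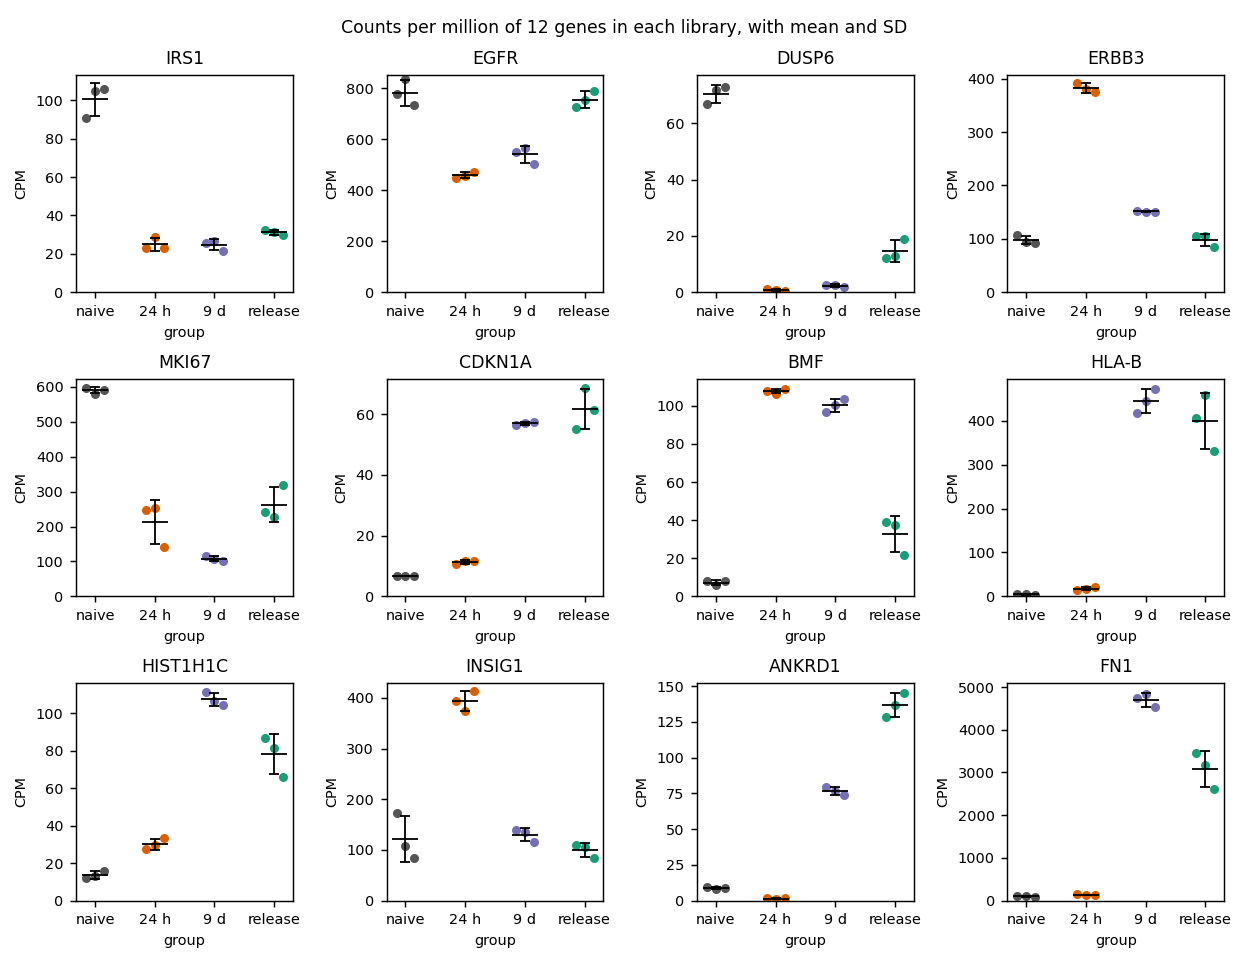
Levels in CPM of 12 genes in the 4 groups, on linear axes from 0, with 1 point per library and bars at the mean ± SD of 3 libraries. IRS1 and DUSP6 are lower in the 3 groups with gefitinib or release than in naive cells, and HLA-B and FN1 have their highest means at 9 d.

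Of the 2210 genes at least 2-fold higher at 9 d than in naive cells, 2025 (91.6%) were still called higher after release, at any fold. On release 1267 (57.3%) fell, 184 were no longer called against naive cells and 1 was lower. Of the 1448 genes at least 2-fold lower at 9 d, 1339 (92.5%) were still called lower, at any fold. On release 1170 (80.8%) rose, 106 were no longer called and 3 were higher. The 2-fold limit was not applied after release, when 1560 genes in all were at least 2-fold higher than in naive cells and 465 lower. Of all tested genes, 64.3% were called in release against naive cells. Among all calls, 2605 genes were higher at 9 d and then fell on release, where independent calls would give 1145, and 3096 were lower and then rose, against 1318. The simulated unchanged groups, with hardly a call, gave means of 0.1 and 0. Both comparisons use the 9 d libraries, so part of this excess may come from shared libraries. After release 4577 genes were higher and 4412 lower than in naive cells by edgeR's quasi-likelihood test, 1560 and 465 of them by at least 2-fold, and camera called 12 lists higher and 11 lower, 0 with an estimated correlation. Counts adjusted over the list alone differed in 8 lists, by at most 2 members. The share of higher calls depends on the scaling: 50.9% here, 46.8% with median-ratio size factors and 60.9% with library totals.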

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

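The tests of explanations and the splits in this part were chosen only after the result was seen, while the comparison of 9 d with 24 h was planned. Cells on gefitinib for 24 h and for 9 d moved apart in several genes and gene lists, which is what drew attention to them: each difference between both times was itself tested in the direct comparison. By at least 2-fold, 38 genes were lower at 24 h and higher at 9 d than in naive cells, and 38 were higher and then lower, fewer than the 284 and 245 that independent calls would give. These genes were picked for lying on opposite sides of naive cells, so they differ between both times by construction. The direct test removed none of them and adds no support. Among named genes that turned from lower to higher, the log2 fold change between 9 d and 24 h was 5.77 for ANKRD1, 4.91 for COL5A1, 4.61 for IL1A, 2.71 for SOCS2 and 2.36 for F3. List medians of 9 d against 24 h were 1.83 for immediate early genes, 1.63 for histones, 1.62 for NF-kB genes, 1.23 for antigen presentation, 1.21 for ERK output, 0.97 for mesenchymal genes, 0.94 for interferon response, 0.76 for MYC targets, 0.65 for ATF4 targets and 0.42 for YAP/TEAD targets. Medians were lower for cholesterol synthesis (−1.04), alveolar and airway genes (−0.98), G2/M genes (−0.97), NRF2 targets (−0.69), fatty acid synthesis (−0.60), epithelial genes (−0.45), FOXO targets (−0.31) and oxidative phosphorylation (−0.17). None of these 18 lists was called with an estimated correlation, where the smallest adjusted p was 0.265. Groups of 3 were not tested for a single library apart from the others.

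Histone transcripts rose at 9 d, by a median of 3.13, while the cells' division genes fell. A higher share of cells in S phase is argued against by the G1/S genes, whose median was −1.90. Weaker selection for polyadenylated RNA at 9 d would raise other RNAs without a poly(A) tail. Of these, 23 had a median of −1.04 (SD 0.92), with 0 higher and 16 lower. All but RMRP were small nucleolar RNAs, and some may themselves be made less. Their fall therefore does not decide whether the selection differed. A rise confined to the histone genes that were chosen is argued against by the tested histone genes outside the list. Of these, 5 of 8 were higher and 0 lower, with a median of 2.15. How far the rise extends stays open, since HIST1H2AG, HIST1H2BJ and HIST2H2BC were not called and genes with too few counts were not tested. A shift towards polyadenylated histone transcripts in cells that have left the cycle may account for the pattern and was not tested.

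Interferon and antigen presentation genes were high at 9 d and stayed high after release. Whether leukocytes were among the cells stays open. The 5 of 17 members of the leukocyte list with a higher mean at 9 d, ITGAM and CSF1R among them, added 10.6 CPM. This lies between the bounds of 4.45 and 44.5 CPM set for the test from the 445 CPM of HLA-B. The sum takes only members that rose, so it cannot be negative, and it does not decide the question. The other members had no higher mean at 9 d, and the leukocyte transcript LAPTM5 fell. PTPRC was at 0.285 CPM and TYROBP at 0. Reads shared between HLA genes would leave other members unchanged, and 41 of 44 members outside that family were higher after release. Most of these members are interferon response genes. Their rise does not show whether HLA reads were assigned to the right HLA gene. Other scalings of the libraries left the interferon median after release at 1.46 or above, against 1.5. In this comparison they moved the median of all genes by only −0.042 and 0.1, so they could hardly have moved the list. The check shows that the choice among these scalings does not account for the rise. It does not address a change in total RNA per cell. Signalling by interferon or NF-kB within the treated cells may underlie the pattern, and no test here separates it from differences in culture handling.

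Sterol genes were high at 24 h and no longer at 9 d. With other scalings of the libraries the median of 9 d against 24 h came no nearer to 0 than −0.97, against −1.04. These scalings moved the median of all genes by only −0.018 and 0.069, so this outcome could hardly have differed. The choice among them thus does not account for the fall, and a change in total RNA per cell is not addressed. Spread between the naive libraries was wide, with mean log2 CPM of the list from 6.43 to 7.24, and the lowest 24 h library was still 0.62 above the highest naive library. In 22 of 23 sterol genes all 24 h libraries lay above all 9 d libraries. The time since medium and serum were last changed may differ between groups, and nothing in the labels or tables tests it, so it stays open beside an effect of the drug.

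The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. The real split gave 10799 called genes at 24 h against naive, 10515 at 9 d against naive, 6558 for release against 9 d, 8989 for release against naive and 9114 at 9 d against 24 h, while the highest of the other splits gave 0 in each, so 1 of 10 splits gave as many. For gene lists the real split and the highest other were 15 and 14 at 24 h, 17 and 17 at 9 d, 12 and 15 for release against 9 d, 23 and 17 for release against naive, and 18 and 15 at 9 d against 24 h, and 1, 3, 4, 1 and 1 of the 10 splits gave as many. Camera with its preset correlation thus calls 6 to 17 lists in splits in which edgeR calls 0 genes. These splits keep 2 libraries of 1 group against 1, so part of the real contrast remains in them and they give no value for unchanged groups.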

How the results depend on the processing

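The fit with a block by column order was chosen after the data were seen, and all others before. The labels number the libraries from 35 to 46 and pair none of them, while the deposited table lists them in 3 sets with 1 library of each group. Deviations from the group means correlated between libraries of the same set by −0.167 to 0.208 (median 0.042), and 7 of 12 libraries were closest to their own set, a hint from the data that does not show pairing. With the sets as a block, 5508 genes were higher and 5392 lower at 24 h, 5415 and 5213 at 9 d, 3665 and 3071 for release against 9 d, 4647 and 4468 for release against naive, and 4878 and 4346 at 9 d against 24 h, and no call of a named gene or list was lost. Of the named genes and lists that were called, none turned its direction under any setting tried. Other genes were not followed. The balance of calls did: for release against 9 d 54.5% were higher, and 47.7% with RLE and 46.1% with totals, and for release against naive 50.9%, and 46.8% with RLE. Of 13428 values of named genes under alternatives, 13317 kept their call and 111 lost it, most often at an adjusted p under 0.01 (23) and without release replicate 3 (14 genes and 5 lists). Calls lost with library totals numbered 5 genes and 7 lists, with DESeq2 8 genes, with limma-voom 2 and with RLE factors 1 gene and 1 list. Of 850 list values without the estimated correlation 826 kept their call. With an estimated correlation 85 of 85 lists lost it, so that 0 lists were called higher and 0 lower in each comparison. The smallest adjusted p was then 0.249 to 0.265. Lists with a low estimate lost their call too. For fatty acid oxidation at 24 h the estimate was −0.031, below the preset, and the camera adjusted p went from 0.0283 to 0.285. For interferon response at 9 d the estimate was 0.052, and it went from 5.11e-09 to 0.249. The cause of the loss was not tested, and it is no measure of correlation between genes. Fry called more lists: 19 higher and 15 lower at 24 h, 22 and 16 at 9 d, 14 and 12 for release against 9 d, 24 higher after release against naive, and 22 and 13 at 9 d against 24 h. A filter of 10 CPM in 3 libraries tests fewer genes, and calls of at least 2-fold were then 1375 higher at 24 h, 1300 higher at 9 d, 111 lower for release against 9 d, 839 higher and 243 lower for release against naive, and 656 higher and 553 lower at 9 d against 24 h. With calls of at least 2-fold the overlaps were 1454 higher and 925 lower at both times, 38 and 38 opposite, 248 higher and then lower on release, and 360 lower and then higher, a count smaller by the construction of the threshold. Over all tested genes the distances were 1.13 from naive to 24 h, 1.13 to 9 d and 0.86 to release, 0.83 from 24 h to 9 d, 0.94 from 24 h to release and 0.46 from 9 d to release, smaller because less variable genes enter.

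Single libraries or scaling decided these list calls (adjusted p without the library or with the scaling). Each range is over the camera alternatives of that list, up to the value with an estimated correlation, and leaves out fry. Histones at 24 h (median 1.45, adjusted p = 0.0461, and adjusted p = 0.34 with an estimated correlation) gave 0.0625 with library totals, 0.0505 without naive replicate 1 and 0.0618 without 24 h replicate 2 (range 0.0315 to 0.34). Immediate early genes at 9 d (0.0439) gave 0.0598 with totals and 0.0636, 0.0504 and 0.0546 without naive replicate 1, naive replicate 3 and 9 d replicate 1 (range 0.022 to 0.52). For release against 9 d, histones (0.0484) gave 0.0659 with RLE, 0.0681 with totals and 0.0621, 0.0607, 0.0551 and 0.095 without 9 d replicates 1 and 3 and release replicates 1 and 3 (range 0.0274 to 0.34), and antigen presentation (0.0307) gave 0.10 without release replicate 3 (range 0.0106 to 0.52). For release against naive, with totals, without naive replicate 1 and without release replicate 3, pro-apoptotic genes (0.0484) gave 0.0668, 0.0873 and 0.0721 (range 0.0215 to 0.359), fatty acid synthesis (0.0461) 0.054, 0.0981 and 0.0793 (range 0.00449 to 0.554), and unfolded protein genes (0.0375) 0.0763, 0.0636 and 0.0934 (range 0.017 to 0.52). WNT and BMP genes (0.0341) gave 0.0638 with totals (range 0.0248 to 0.285). The cause was not tested. At these depths a gene with 0 counts in a group of 3 libraries allows a level of up to 0.0639 CPM in naive cells, so folds of genes near that floor are limited by counting.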

Other observations

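The lists and rules named below were fixed before the data were examined, and the genes said to be chosen for their values were not. After release, senescence and secretory genes were higher than in naive cells in 11 of 17 cases and lower in 2 (median 0.88, camera adjusted p = 0.00514, and adjusted p = 0.265 with an estimated correlation), IL6 at 9.14 ± 1.25 CPM against 0.618 ± 0.320 CPM. LMNB1, a nuclear lamina protein that falls in senescent cells, had been 26.4 ± 2.83 CPM at 9 d and rose to 71.8 ± 9.56 CPM on release. WNT and BMP/TGF-beta genes were higher after release in 12 of 21 cases and lower in 2 (median 0.53, camera adjusted p = 0.0341, and adjusted p = 0.285 with an estimated correlation), a call lost with library totals (adjusted p = 0.0638, with 0.0248 to 0.285 over all camera alternatives). ID3, a BMP target, was 13.2-fold higher, at 46.5 ± 1.32 CPM, and TCF7, a WNT transcription factor, was 12.1 ± 0.674 CPM against 41.6 ± 2.78 CPM. At 9 d neither list was called (adjusted p = 0.0956 and 0.0549). Of the NOTCH list 3 genes rose and 6 fell at 9 d, and the list was not called (median −0.38, adjusted p = 0.432), with the ligand JAG1 at 23.2 ± 0.736 CPM against 98.6 ± 10.6 CPM. Chromatin regulators went both ways at 9 d, 9 higher and 10 lower (median −0.04, adjusted p = 0.634): HDAC5, a class II deacetylase, rose 6.72-fold, and EZH2, the histone methyltransferase of Polycomb, fell from 88.9 ± 3.90 to 24.0 ± 1.16 CPM. Of p53 target genes 11 rose and 7 fell at 9 d (median 0.45, adjusted p = 0.246). CA9, a hypoxia-induced carbonic anhydrase, had 0 counts at 9 d and was at least 276-fold lower than in naive cells, in a hypoxia list that was not called (median −0.42, adjusted p = 0.134).

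Some genes moved in opposite directions at both times on drug. The following were chosen for their values, given as log2 fold changes against naive cells at 24 h and at 9 d. RASGRP1, an activator of RAS, had −2.08 ± 0.73 and 5.98 ± 0.21. With a mean of 6.55 CPM over all 12 libraries, its levels in naive and 24 h cells were low. Its fall at 24 h is therefore limited by counting. BMP6 had −2.25 and 2.84, INHBA, a subunit of activin, −2.76 and 2.01, and THBS1, a matrix protein, −1.75 and 1.03. In the other direction AGR2, a protein of the secretory pathway, had 1.66 and −2.09, TRIM31 2.11 and −2.19, and CASP14 1.28 and −2.17. Of histone genes outside the list, HIST2H2BF had 4.58 at 9 d and HIST1H4E 2.43, while HIST1H2AG (0.36), HIST1H2BJ (0.40) and HIST2H2BC (−0.44) were not called.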
